A study of Mus musculus with 6 samples.

How the data were processed

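RNA from mouse liver was measured by RNA sequencing in 6 libraries, 3 from mice labelled Sox9HKO (called HKO below) and 3 from Sox9f/f mice (called WT below), all from 12-week-old C57BL/6 animals, 48 h after partial hepatectomy (PHx), the surgical removal of part of the liver that sets off regrowth. The labels give the tissue as liver and the cell type as hepatocyte. Per the labels' protocols, total RNA was checked for integrity and cleaned on beads with a DNase step. The mRNA was then separated and fragmented, and the libraries were made by end repair, A-tailing and adapter ligation. No strand-marking step is described, so reads from a gene and from an antisense partner that overlaps its exons cannot be told apart. The labels do not say whether each library came from its own mouse, so p-values measure the spread between these libraries only.

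Per the submitters' processing notes, the tools were HISAT2 2.0.4 and StringTie 1.3.0 and the builds were mm10 and GRCm38.p4. The notes do not give the role or the settings of either tool. The authors deposited 1 table with a whole-number read count and an FPKM (fragments scaled by gene length and library total) for each of 34745 Ensembl genes in each library, per the file headers. The counts are not normalized. In all 9308 genes with at least 50 counts in every library, the deposited FPKM equals the count divided by the column total and by 1 length per gene, with implied lengths that differ between libraries by less than 0.1%. How reads matching several genes were assigned is not given in the sources used here, so values of near-identical genes (the Mup family, Saa1 and Saa2, Cyp2a4 and its close relatives, Cyp4a10 and Cyp4a31, histone and immunoglobulin genes) are uncertain. Coordinates are those of the deposited table, counted from 1, on GRCm38. Of the table's genes, 98.8% were found by identifier in the GENCODE M21 annotation of that build, which gave the biotypes and the exon overlaps. Of the genes found, 80.9% have the same coordinates there, so overlaps of the others rest on gene models that differ from the table's. Exons of Nr1d1 overlap Thra, those of Cyp51 overlap Akap9, those of Pdia6 overlap Atp6v1c2, those of Hexa overlap Tmem202, those of Gt(ROSA)26Sor overlap Thumpd3, those of Plin4 overlap Hdgfl2, those of Csf1r overlap Hmgxb3, those of Timp3 overlap Syn3, those of Nr1i3 overlap Tomm40l, those of Atp5d overlap Cbarp, those of Plk3 overlap Tctex1d4, those of Ppp1r15a overlap Tulp2 and those of Cela2a overlap Casp9, each on the opposite strand, and those of Abcg5 and Abcg8 overlap each other, so these values are uncertain too. The exons of Hist1h2al, Cyp2a4, Rgs16, Usp2, Fgg, Alas1, Arntl, Acot3, Oasl1, Pkhd1, Vcam1 and Ctgf overlap predicted or unnamed antisense genes, those of Cela2a also overlap Ctrc on the same strand, and those of Col3a1, Rhbg, Spp1, Hspa8 and Pdia4 overlap predicted or small RNA genes on the same strand.

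The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr on the groups (12556 of 34745, with 16194 at 0 in every library), libraries were scaled by TMM, and HKO was compared with WT by the quasi-likelihood F-test without a block. Every p-value of a gene was adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p below 0.05. Fold changes are HKO minus WT on the log2 scale, and each standard error is the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM (counts scaled to a common library total), as mean ± SD over 3 libraries. For a gene at 0 in a whole group, the fold is a lower bound against 3 counts over that group, which covers counting error only. The 6 libraries hold 16659778 to 21168233 counts.

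For the text, 46 gene lists were fixed before the data were examined: cell cycle, signalling, zonation, liver metabolism, translation, stress, immune, sex-biased, clock and matrix genes, and markers of other cell types a liver sample can hold. Of their 1343 entries, 1335 were matched by symbol or older symbol. The 40 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with p-values adjusted over the lists. Beside this, camera with a correlation estimated from the data and fry were run. Regrouping the 6 libraries gave many list calls with the preset correlation in groupings that mix the genotypes (values under Other observations). Each such grouping holds the genotypes in unequal numbers, so part of the genotype difference stays between its groups. These calls thus do not measure false calls. No list passed with an estimated correlation, so the camera p-values are descriptive. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. KEGG pathways named in the deposited table were tested by Fisher's exact test, one-sided, among 5030 tested genes with a pathway, for 304 pathways of at least 10 such genes and both directions, with p-values adjusted over the 608 tests. This test was chosen after seeing the data. It treats genes as independent, although genes of a pathway can vary together, so its p-values are descriptive too.

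The named genes follow a rule fixed before the data were examined. They are Sox9; the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM, no overlap between the HKO and WT values and no predicted or clone name; and, of each list described, up to 4 called members with the smallest p, or up to 2 members given as values where none was called. A few genes that the rule covers are not reported here. Genes named outside the rule are marked as chosen after their values were seen. The Sox9 level was also compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

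Alternatives fixed before the data were examined were DESeq2 size factors, library totals without further scaling, no filter beyond 1 count, a mean of at least 5 CPM, a block on the replicate number, each library left out in turn, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) for genes with an FPKM of at least 0.5 in 3 libraries, and an added fold threshold. For lists they were an estimated correlation, fry and a prior count of 0.5. A fit without the 13 mitochondrial genes was added after seeing the data. The steps were tested on simulated counts with the real genes' means, dispersions and library sizes and 200 changed genes. For HKO against WT in 12380 simulated genes, the test recovered 50.5% of 99 genes with a log2 change of 1 and 89.7% of 97 genes with a log2 change of 2, with 8 false calls among 145. Only 200 genes changed, far fewer than were called in the data, so the share recovered is not the sensitivity of the real comparison. A list planted in the simulated counts was recovered, and none of the other 38 lists tested was called. The simulated genes were drawn independently of each other, so this says nothing about false calls for lists whose genes vary together.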

Results

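Gene expression was measured in liver RNA of mice labelled Sox9HKO (HKO, 3 libraries) and of Sox9f/f mice (WT, 3 libraries), 48 h after PHx. Sox9 encodes a transcription factor of bile duct cells and of the progenitor-like hepatocytes that appear after liver injury. The libraries held 18136185, 18389222 and 21168233 counts (HKO 1, 2 and 3) and 17032057, 18514962 and 16659778 counts (WT 1, 2 and 3), with a count in 15509 to 16284 genes each. The first principal component of log-CPM carried 57.7% of the variance and separated HKO from WT. The second carried 18.8% and set HKO 2 apart from the other HKO libraries. The 13 mitochondrial genes took 25.9% of the counts in HKO 2 and between 12.1% and 16.3% in the other 5 libraries.

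The targeted gene was lower in HKO. Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760, plus strand) was at 5.14 ± 1.06 CPM in HKO and 10.6 ± 3.41 CPM in WT (SD, n = 3), which is 48.3% of the WT mean, with a log2 fold change of -1.05 (SE 0.27, adjusted p = 0.0284). Its level was 6.34, 4.30 and 4.78 CPM in HKO 1, 2 and 3 and 6.94, 13.7 and 11.4 CPM in WT 1, 2 and 3. All 3 HKO values thus lay below all 3 WT values, and WT 1 lay close to HKO 1. The two-sided exact permutation p was 0.1, the smallest this design allows. The call was lost when HKO 2, HKO 3, WT 2 or WT 3 was left out (adjusted p = 0.0503, 0.0862, 0.0929 and 0.0975) and with a block on the replicate number (log2 fold change -1.02, adjusted p = 0.0652). Which exons the allele removes is not given in the sources used here, so reads from retained exons can be among these counts. The labels give the tissue as liver and the cell type as hepatocyte, and whether whole liver or a hepatocyte preparation was sequenced is not given in the sources used here, so the counts can include Sox9 of other cells such as bile duct cells.

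The comparison of HKO with WT asks how the mRNA profiles of these samples after PHx differ with the Sox9 genotype. In HKO, the called genes of the lists of mitosis (45 of 53 tested), cholesterol synthesis (20 of 25), the acute phase (15 of 29) and the interferon response (19 of 45) were all lower, and those of fatty acid oxidation (31 of 37) were all higher. In the joint list of gluconeogenesis, the urea cycle and amino acid breakdown 24 of 35 were higher and 2 lower. As whole lists these 6 were past the threshold by camera with its preset correlation, and none was with an estimated correlation. By fry, which does not compare a list with other genes, all 6 were past it (adjusted p from 0.000198 to 0.0368). Cyclin B1 (Ccnb1) fell from 24.4 ± 3.18 to 4.55 ± 1.42 CPM, the acute phase gene Saa2 fell from 4579 ± 461 to 311 ± 29.2 CPM, and the fatty acid hydroxylase gene Cyp4a14 rose from 69.5 ± 19.5 to 777 ± 108 CPM (SD, n = 3). Of 12556 genes tested, 1516 were higher and 1401 lower in HKO at an adjusted p below 0.05, or 23.2% of the genes. Of these, 529 were at least 2-fold higher and 554 at least 2-fold lower. The HKO and WT values did not overlap in 5549 of the tested genes (44.2%), where chance gives 10%. Without WT 3 the counts were 722 higher and 682 lower, without WT 2 they were 952 and 894, and without HKO 3 they were 969 and 907. Without HKO 2, the library that stood apart, they were 1589 and 1546. Counts within lists fell too with a library left out, for example in the G2/M and mitosis list from 45 lower to 20 without WT 3.

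**Figure D1:**
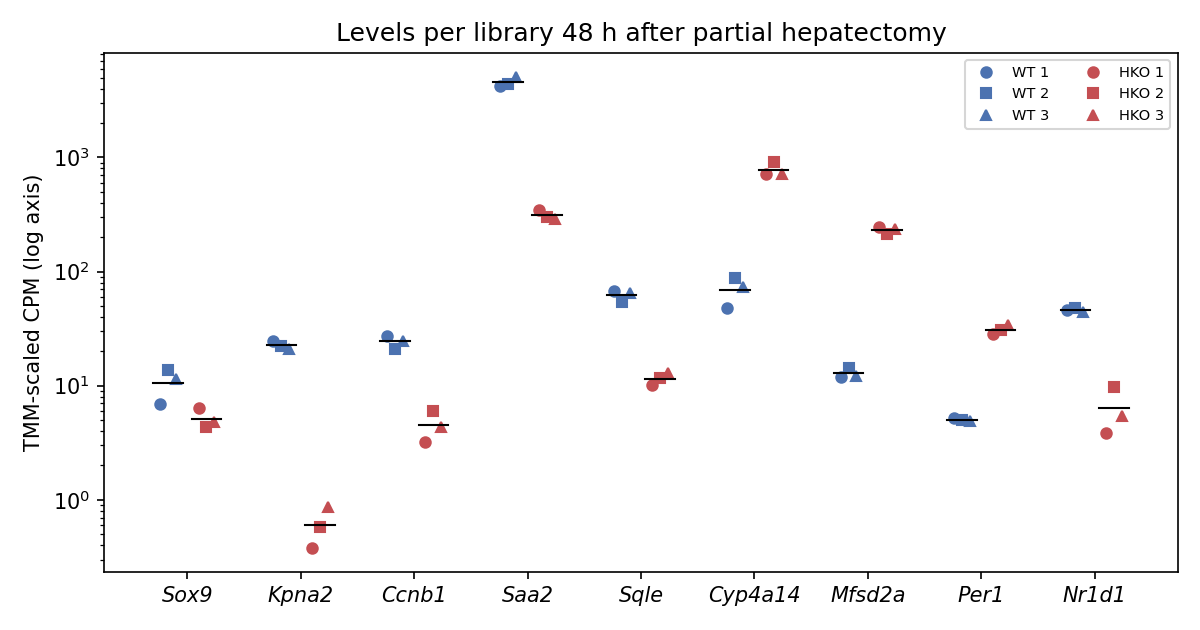
TMM-scaled CPM on a log axis for 9 genes in each of the 6 libraries, with WT in blue, HKO in red, marker shape for the replicate number and a black bar for the mean of 3 libraries. Sox9 in WT 1 (6.94 CPM) lies next to HKO 1 (6.34 CPM), while for Saa2 the means are 4579 CPM in WT and 311 CPM in HKO.

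The 10 largest rises included genes of lipid handling and immunoglobulin genes. Cyp2a4, a steroid hydroxylase gene with higher expression in female mouse liver, rose from 0.880 ± 1.12 to 194 ± 35.0 CPM (log2 fold change 7.75, SE 0.60, adjusted p = 0.000298, and 9.64 without WT 1). Mfsd2a, which encodes a transporter of lysophosphatidylcholine, rose from 12.8 ± 1.29 to 232 ± 15.0 CPM (log2 fold change 4.17, SE 0.12) and had the smallest adjusted p of all genes, 8.30e-06. Cidec, a lipid droplet protein gene 0.357 Mb from Gt(ROSA)26Sor, rose from 1.36 ± 0.855 to 27.5 ± 5.35 CPM (log2 fold change 4.32). Ppp1r3g, which encodes a subunit that directs a phosphatase to glycogen, rose with a log2 fold change of 4.19, and Igsf23, Rasd1 and Rgs16 rose with values of 4.27, 4.18 (3.22 without HKO 2) and 3.96. The immunoglobulin heavy chain genes Ighm and Ighg2c rose with log2 fold changes of 4.38 and 4.16. Ighg2b was at 0 in all 3 WT libraries and at 2.68 ± 2.23 CPM in HKO, at least 46.6-fold higher against 3 counts over the WT group. Ighg2b stood at 1.67, 5.23 and 1.14 CPM in HKO 1, 2 and 3, and without HKO 2 the bound is at least 24.4-fold.

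The 10 largest falls included acute phase and urinary protein genes. Kpna2, an importin alpha gene that is high in dividing cells and lies 5.79 Mb from Sox9, fell from 22.6 ± 1.88 to 0.608 ± 0.246 CPM (log2 fold change -5.17, SE 0.24, adjusted p = 6.94e-05). The protease inhibitor gene A2m, 8.57 Mb from Gt(ROSA)26Sor, fell from 11.4 ± 1.21 to 0.148 ± 0.128 CPM (log2 fold change -6.28), and the clock gene Npas2 fell from 3.39 ± 1.02 to 0.0552 ± 0.0538 CPM (log2 fold change -5.84, and -5.23 without HKO 3). Apol10b, Saa2 and Crybb3 fell with log2 fold changes of -5.70, -3.88 and -3.53 (Apol10b -5.11 and Crybb3 -2.90 without HKO 3), and the call of Crybb3 was lost without WT 2 or WT 3 (adjusted p = 0.0636 and 0.0760). The major urinary protein genes Mup17, Mup18 and Mup15 fell with values of -4.92, -4.67 and -4.48, and with -3.70, -3.63 and -3.28 without WT 1. Mup17 stood at 346, 19.8 and 117 CPM in WT 1, 2 and 3. Limma-voom no longer called Mup15 and Mup18 (adjusted p = 0.0506 and 0.0893). Hist1h2al, annotated as a processed pseudogene of a histone, was at 0 in all 3 HKO libraries and at 7.69 ± 0.384 CPM in WT, at least 148-fold lower in HKO against 3 counts over the HKO group.

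Genes of mitosis were lower in HKO. Of 53 tested genes of the G2/M and mitosis list, 45 fell, 8 did not pass the test and none rose, with a median log2 fold change of -1.96, and 51 fell when adjusted over the list alone. Ccnb1, Cks2, Dlgap5 and Cenpf, which serve mitotic entry, cyclin-dependent kinase function, the spindle and the kinetochore, fell with log2 fold changes of -2.43, -1.08, -1.90 and -2.69. The list lay lower than other genes by camera (adjusted p = 4.76e-17), and this call was lost with an estimated correlation (adjusted p = 0.551 with an estimated correlation). Relative to the WT mean, the list's median on the log2 scale was -0.98 in HKO 2, -2.81 in HKO 1 and -2.58 in HKO 3, and without HKO 2 the median log2 fold change was -2.80 with 51 genes lower.

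Fewer genes of DNA replication passed the test. Of 45 tested S phase genes 6 were lower and none was higher, with a median log2 fold change of -0.48 (camera adjusted p = 1.90e-05, and adjusted p = 0.685 with an estimated correlation). E2f2, a transcription factor gene of the cell cycle, fell with a log2 fold change of -1.93, and Dbf4, which activates the kinase that fires replication origins, with -1.53. Adjusted over the list alone, 2 fell. The S phase median of HKO 2 was -0.04 relative to WT, and when HKO 2 was left out 29 genes fell and the median was -0.80, while 2 or 3 fell when any other library was left out. Of 19 tested genes of the G1 and immediate early list 6 were higher, among them Myc (log2 fold change 1.35), and 13 did not pass, with 6 higher when adjusted over the list alone. Without HKO 2 the list had 2 genes higher and 1 lower, and without WT 3 it had 1 higher. This list was past the threshold by camera (adjusted p = 0.0314) but not with an estimated correlation (adjusted p = 0.685 with an estimated correlation), without HKO 2 (adjusted p = 0.154) or without WT 1 (adjusted p = 0.0973).

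Genes of fatty acid oxidation and targets of the nuclear receptor PPAR-alpha were higher in HKO. Of 37 tested members 31 rose, none fell and 6 did not pass, with a median log2 fold change of 0.88, and 35 rose when adjusted over the list alone. The hydroxylase genes Cyp4a10, Cyp4a31 and Cyp4a14 rose with log2 fold changes of 2.95, 2.22 and 3.48, and the thioesterase gene Acot2 with 2.37. The median stood between 0.83 and 0.95 in each of the 3 HKO libraries relative to WT. By camera the adjusted p was 1.38e-17 (adjusted p = 0.173 with an estimated correlation).

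Genes of cholesterol synthesis were lower. Of 25 tested members 20 fell, none rose and 5 did not pass, with a median log2 fold change of -1.34, and 22 fell when adjusted over the list alone. Sqle, Cyp51 and Dhcr7, enzymes of the sterol pathway, fell with log2 fold changes of -2.44, -2.38 and -1.73, and Insig1, a sterol sensor of the endoplasmic reticulum, with -1.79. Camera gave an adjusted p of 7.89e-12 (adjusted p = 0.353 with an estimated correlation). In the list of fatty acid and triglyceride synthesis 11 of 29 tested members rose, 2 fell and 16 did not pass, with a median of 0.47. The rises were led by the lipid droplet coat genes Plin4 (log2 fold change 2.80) and Plin5 (1.61), by Cidec, and by the desaturase gene Fads2 (1.13). Adjusted over the list alone 14 rose and 3 fell (camera adjusted p = 0.000539, and adjusted p = 0.270 with an estimated correlation).

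Genes of gluconeogenesis, the urea cycle and amino acid breakdown were higher, 24 of 35, with 2 lower and a median log2 fold change of 0.91. Tat, Got1 and Cth, enzymes of tyrosine, aspartate and cysteine metabolism, rose with log2 fold changes of 1.82, 1.96 and 1.84. Adjusted over the list alone 26 rose and 2 fell (camera adjusted p = 2.24e-09, and adjusted p = 0.551 with an estimated correlation). In the glycolysis list 11 of 21 genes rose and 2 fell, among them Pfkfb3 (log2 fold change 2.16), which makes the allosteric activator of phosphofructokinase, and the lactate transporter gene Slc16a1 (-0.91). There, 13 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.000302, and adjusted p = 0.353 with an estimated correlation).

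Acute phase and interferon-stimulated genes were lower in part. Of 29 tested acute phase genes 15 fell, 14 did not pass and none rose, over all genes and adjusted over the list alone, with a median of -0.57. Saa2 and Saa1, which encode serum amyloid A, fell with log2 fold changes of -3.88 and -2.89, the pentraxin gene Apcs with -1.37 and the metalloreductase gene Steap4 with -1.09. Camera gave an adjusted p of 9.12e-07 (adjusted p = 0.565 with an estimated correlation). Of 45 tested gene records of the interferon list 19 fell, 26 did not pass and none rose, with a median of -0.48 and 21 lower when adjusted over the list alone. Zbp1, a nucleic acid sensor, Oasl1, and Stat2, a transducer of interferon signals, fell with log2 fold changes of -1.40, -1.35 and -0.84 (camera adjusted p = 2.36e-06, and adjusted p = 0.173 with an estimated correlation).

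The list of the unfolded protein and integrated stress responses had more genes lower than higher. Of 30 tested members 15 fell, 5 rose and 10 did not pass, over all genes and adjusted over the list alone, with a median of -0.49. The falls were led by the chaperone and disulfide isomerase genes Sdf2l1, Pdia4, Pdia6 and Dnajb11, with log2 fold changes of -1.80, -1.12, -1.59 and -1.08. The 5 that rose were Ddit4, Asns, Sesn2, Herpud1 and Ppp1r15a, with log2 fold changes of 1.82, 1.33, 0.94, 1.46 and 0.85, named after their values were seen. The call of Ppp1r15a was lost when any library but HKO 3 was left out (adjusted p from 0.0618 to 0.147). Camera gave an adjusted p of 0.00136 (adjusted p = 0.374 with an estimated correlation).

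Clock genes differed in both directions. Of 22 tested members 12 rose and 3 fell, with a median log2 fold change of 0.78. Per1 and Per2, which repress the clock's activators, rose with values of 2.62 and 2.55, and the deubiquitinase gene Usp2 with 2.86. The 3 that fell were Npas2, Nr1d1 (log2 fold change -2.87) and Arntl (-1.47), the last pair named after their values were seen. Adjusted over the list alone 14 rose and 3 fell (camera adjusted p = 0.000302, and adjusted p = 0.173 with an estimated correlation). The hour of collection is not given in the sources used here.

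Hepatocyte identity genes gave no common direction. In the list of liver-enriched transcription factors and plasma protein genes 5 of 30 rose and 5 fell, with a median of -0.02, or 0.07 without HKO 2 (7 and 5 when adjusted over the list alone). Nr1i2, a receptor for foreign compounds, rose with a log2 fold change of 0.95, and the fibrinogen genes Fgg, Fgb and Fga, which also respond in the acute phase, fell with -1.36, -1.40 and -1.28. In the biliary and progenitor list, which includes Sox9 itself, 3 of 12 genes fell and 1 rose, over all genes and adjusted over the list alone, with a median of 0.01 and a mean of -0.17. The median was -0.23 without HKO 2, and relative to WT the list's medians were -0.29, 0.18 and -0.28 in HKO 1, 2 and 3. Spp1, which encodes osteopontin, fell with a log2 fold change of -2.03 and Pkhd1, a gene of the biliary cilium, with -1.03, while Tm4sf4 rose with 0.63. The call of Pkhd1 was lost without WT 2 or WT 3 (adjusted p = 0.0774 and 0.0805). Neither list was past the threshold by camera (adjusted p = 0.516 and 0.561).

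Markers of other cell types also differed between the groups. Of 20 tested Kupffer cell and macrophage genes 16 rose and 1 fell, with a median of 0.86, and 17 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.18e-06, and adjusted p = 0.551 with an estimated correlation). Cd163, Csf1r and Lyz2 rose with log2 fold changes of 1.29, 1.13 and 0.96, and Mpeg1, a macrophage perforin gene, fell with -1.43. Of the 4 tested B and plasma cell genes, too few for the list test, Ighm, Igkc and Jchain rose with 4.38, 3.59 and 2.85 and Ly6d fell with -0.63. These 4 were also past the threshold when adjusted over the list alone.

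The medians of endothelial, stellate cell and matrix genes were highest in HKO 2. Relative to WT they were 2.06, 1.98 and 2.42 on the log2 scale in HKO 2, against 0.31, 0.18 and 0.19 in HKO 1 and 0.59, 0.37 and 0.41 in HKO 3. The collagen gene Col3a1, named after its values were seen, stood at 137 CPM in HKO 2 and between 8.38 and 18.7 CPM elsewhere. Over all genes 2 of 22 endothelial, 6 of 18 stellate and 5 of 27 matrix genes rose and none fell, and adjusted over the list alone 16, 7 and 3 rose. Lyve1, an endothelial hyaluronan receptor gene, rose with a log2 fold change of 1.82, and the inhibitor of matrix proteases Timp3 with 2.39 (1.77 without HKO 2). All 3 lists were past the threshold by camera (adjusted p = 0.000302, 0.0173 and 0.000807) but not with an estimated correlation (adjusted p = 0.685, 0.745 and 0.685 with an estimated correlation). Without HKO 2 the endothelial list stayed past the threshold (adjusted p = 0.000766), the stellate and matrix calls were lost (adjusted p = 0.294 and 0.113), and the medians of the 3 lists were 0.40, 0.37 and 0.33. The genes higher were then 3, 6 and 4, with 1 stellate gene lower. Without WT 3, 1 endothelial, 0 stellate and 2 matrix genes were higher. The pancreatic acinar gene Cela2a stood at 101 CPM in HKO 2 and at most at 1.29 CPM in the other libraries, and was not past the threshold (adjusted p = 0.0519), though it passed with a block on the replicate number, with library totals, without a filter, and without HKO 1 or HKO 3 (adjusted p = 0.0428 and 0.0339).

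**Figure D2:**
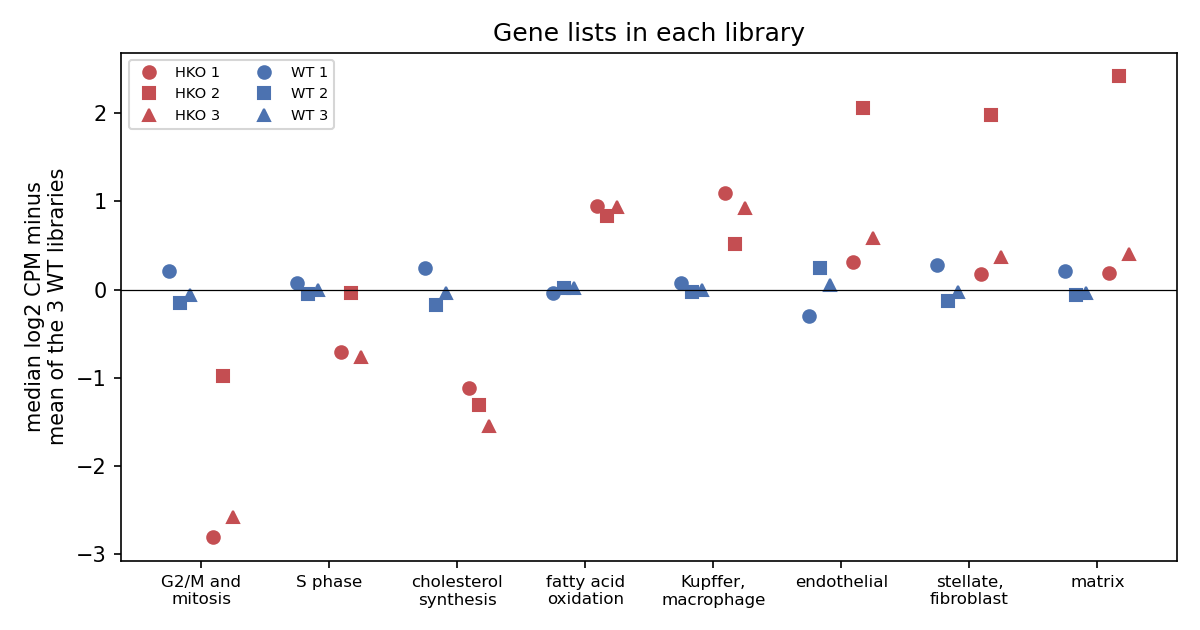
For 8 gene lists, each point is 1 library's median over the list's genes of log2 CPM minus the mean of the 3 WT libraries, with WT in blue, HKO in red and marker shape for the replicate number. HKO 2 lies at 2.42 for matrix genes and at -0.98 for mitosis genes, where HKO 1 and HKO 3 lie at 0.19 and 0.41 and at -2.81 and -2.58.

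Over all 40 lists tested, 19 were higher and 6 lower in HKO by camera with the preset correlation, and none passed with an estimated correlation (5 at an unadjusted p below 0.05), while fry called 14 higher and 5 lower. The pathways of the deposited table, tested after seeing the data, gave 36 pathways with more higher genes than the background and 8 with more lower genes. The pathway test treats genes as independent, so its p-values are descriptive. Fatty acid degradation had 23 of 41 genes higher (56.1% against 15.2% in the background, adjusted p = 4.31e-07, Fisher's exact test), and the lysosome, whose genes are also high in macrophages, had 38 of 111 (34.2%, adjusted p = 3.67e-05). Steroid biosynthesis had 10 of 16 genes lower (62.5% against 10.8%, adjusted p = 6.23e-05), protein processing in the endoplasmic reticulum 42 of 152 (27.6%, adjusted p = 7.03e-07) and the cell cycle 33 of 112 (29.5%, adjusted p = 4.21e-06).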

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

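The fit without mitochondrial genes was chosen after seeing the data and moves almost nothing under TMM, so it says nothing about stability. Requiring a log2 fold change of at least 1 left 529 genes higher and 554 lower. With 1 library left out, the counts ranged from 722 to 1589 higher and from 682 to 1546 lower, and of the 2917 calls 1383 kept their direction and call without WT 3, which leaves fewer samples. Scaling by DESeq2 size factors, library totals, either filter, the block, DESeq2, limma-voom and limma on FPKM kept both counts within 1.5 times, and the scalings moved the median gene by under 0.01. The Sox9 log2 fold change ranged from -1.29 to -0.83 with 1 library left out and was -1.02 with the replicate block (adjusted p = 0.0652, over all alternatives 0.00402 to 0.0975), and the cause was not tested. Equal replicate numbers correlated at -0.002, 0.002 and 0.072 in their deviations from the group means, and unequal numbers at -0.076 to 0.056. With 3 libraries per group this does not settle whether equal numbers pair libraries, and the labels do not say. The block gave 1245 genes higher and 1115 lower. With an estimated correlation 0 lists were higher and 0 lower; the cause was not tested. Sox9 aside, 170 called genes are covered by the naming rule over all lists or added by the text. Of these, 138 stayed called in the same direction under every alternative that gave them an adjusted p, and none reversed. Of 25 called lists, 18 stayed called in every alternative that tested them, other than the estimated correlation and fry. A gene or list dropped by an alternative's filter was not counted as lost there. The alternatives for a table without counts were not run, since counts are present. The simulated test recovered 50.5% of the genes with a log2 change of 1. Far fewer genes changed there than were called in the data, so this share is not the sensitivity of the real comparison.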

Other observations

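Drug-metabolising and lysosomal genes were higher in part in HKO. Of 36 tested P450, glucuronosyltransferase and sulfotransferase genes 17 rose, 2 fell and 17 did not pass, with a median log2 fold change of 0.53 (18 and 2 when adjusted over the list alone). Besides Cyp2a4, these included Por, the electron donor of the P450 enzymes (log2 fold change 2.12), and Ugt1a1, the bilirubin glucuronosyltransferase gene (1.27), whose exons overlap other Ugt1a genes. Of 34 autophagy and lysosome genes 20 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 0.41. Among them were the lysosomal hydrolase genes Gaa (0.77) and Hexa (0.96). Without WT 3, 9 of the 34 rose and 0 fell. The autophagy and lysosome medians relative to WT were 0.53, 0.25 and 0.38 in HKO 1, 2 and 3, in the same order as those of the Kupffer cell and macrophage list (1.09, 0.52 and 0.92), and which cells the lysosomal transcripts come from was not tested. Their camera adjusted p values were 0.000209 and 3.16e-06 (adjusted p = 0.457 and 0.391 with an estimated correlation). Of 27 iron and heme genes 10 rose and 1 fell (12 and 2 when adjusted over the list alone), led by Alas1, the first enzyme of heme synthesis (2.50). That list's camera adjusted p was 0.0356 (adjusted p = 0.353 with an estimated correlation, 0.0639 without HKO 1 and 0.125 without WT 1). Of 31 bile acid genes 10 rose and 3 fell (11 and 5 when adjusted over the list alone), among them the transporter genes Abcc3 (1.48), Abcg5 (1.88) and Abcg8 (1.36), and the list was past the threshold without HKO 2 (adjusted p = 0.0272) but not over all libraries (adjusted p = 0.113).

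Few ribosomal protein genes and no proteasome gene passed the test. Of 61 cytosolic ribosomal protein genes 1 rose and 2 fell, with a median log2 fold change of -0.003, and none of 31 proteasome genes passed the test, with a median of 0.04 (Psmd4 0.34, adjusted p = 0.0622). Without HKO 2, Psmd4 was called (adjusted p = 0.0419) as 1 of 2 proteasome genes higher, and 2 were lower without HKO 1. Adjusted over the list alone, 1 ribosomal gene fell and no proteasome gene was called. Genes higher in male liver went both ways. Of 23 tested, 5 rose and 8 fell, including Selenbp2 (-2.82), Mup7 (-2.24) and Hsd3b5 (-2.20), with 6 and 9 when adjusted over the list alone and a median of 0.01 beside a mean of -0.15. When HKO 2 was left out, 8 rose and 7 fell, with a median of 0.21. Of 16 genes higher in female liver 7 rose and 2 fell (8 and 2 when adjusted over the list alone), including Fmo2 (3.47), Cyp2a4 (7.75) and Acot3 (3.31). The female list was past the threshold (camera adjusted p = 0.0304, adjusted p = 0.364 with an estimated correlation) but not without HKO 2 (adjusted p = 0.269), and the male list was not (adjusted p = 0.484).

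Respiratory chain, periportal and antioxidant genes were higher in part. Of 50 respiratory chain genes 15 rose, over all genes and adjusted over the list alone, and none fell, with a median of 0.30 (0.18 without HKO 1), led by Ndufa6 (0.62) and Atp5d (0.72), and 3 rose without WT 2. Of 28 periportal genes 12 rose and 2 fell, over all genes and adjusted over the list alone, led by the urea cycle genes Ass1 (1.36) and Asl (1.95), and of 32 NRF2 targets and antioxidant genes 10 rose and 1 fell (13 and 1 when adjusted over the list alone), led by Cbr1 (1.46) and the heme oxygenase gene Hmox1 (0.99). Camera gave adjusted p values of 3.16e-06, 0.00378 and 0.000978 (adjusted p = 0.685, 0.685 and 0.565 with an estimated correlation), and the periportal call was lost without WT 1 (adjusted p = 0.0804). Of 20 cytosolic heat shock genes 7 rose and 2 fell (8 and 3 when adjusted over the list alone), led by Hspa8 (1.31). That list's camera adjusted p was 0.0489 (adjusted p = 0.685 with an estimated correlation), and its call was lost when HKO 1, HKO 2, WT 2 or WT 3 was left out (adjusted p = 0.111, 0.0730, 0.125 and 0.0788). Of 5 erythroid genes the 3 globin genes Hbb-bt, Hba-a1 and Hbb-bs rose (5.30, 3.80 and 2.84), over all genes and adjusted over the list alone (camera adjusted p = 0.0246, and adjusted p = 0.353 with an estimated correlation). Their medians relative to WT were 2.12, 3.63 and 1.06 in HKO 1, 2 and 3, and without HKO 2 Hbb-bt, Hba-a1 and Hbb-bs stood at 4.53, 2.31 and 1.84. The 3 WT libraries hold 1 count of Hbb-bt in all, so its fold is poorly defined. Hba-a1 and Hbb-bs lost their calls when WT 1, WT 2 or WT 3 was left out.

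Signalling lists gave no call by camera. Of 20 YAP target genes 4 rose and 1 fell, including Ctgf (2.71) and Axl (0.97), of 13 Notch genes 2 rose and 1 fell, including Lfng (1.93), whose call was lost without WT 3 (adjusted p = 0.0641), and of 26 Wnt target and pericentral genes 4 rose and 3 fell, including Nr1i3 (1.24) and Rhbg (-2.32, and -1.71 without WT 1). Adjusted over the list alone these were 5 and 1, 3 and 1, and 4 and 3, and the camera adjusted p values were 0.370, 0.218 and 0.693. The Wnt list passed, as higher, when WT 1 was left out (adjusted p = 0.0491). Of 21 p53 target and kinase inhibitor genes 4 rose and 5 fell (5 and 5 when adjusted over the list alone), with Plk3 at 2.03 and Cdkn2c at -1.59. Of 24 growth factor and receptor genes 5 rose and 5 fell (6 and 5 when adjusted over the list alone), with Fgf21 at 2.99 and Igfbp2 at 1.11. Of 13 NF-kB target genes 3 rose and 3 fell (4 and 3 when adjusted over the list alone), with Vcam1 at 2.16 and Cxcl1 at -2.34, and of 35 complement and coagulation genes 5 rose and 8 fell (8 and 9 when adjusted over the list alone), with F11 at -1.41 and Mbl2 at -0.85. Their camera adjusted p values were 0.893, 0.474, 0.273 and 0.273, and the complement list passed, as lower, without WT 1 (adjusted p = 0.0294). Of 38 ribosome biogenesis genes 3 rose and 1 fell, over all genes and adjusted over the list alone, with Rrs1 at 0.74 (camera adjusted p = 0.393). Of 6 cholangiocyte genes Spp1 and Pkhd1 fell and none rose (1 rose and 2 fell when adjusted over the list alone), with a median of 0.09, or -0.17 without HKO 2, and a mean of -0.19 (camera adjusted p = 0.675). Of the lists too short for camera, the neutrophil list gave Lcn2 at -1.22, which hepatocytes also make, and Csf3r at 1.78, both called, the latter not when HKO 1, HKO 2 or any WT library was left out. The T cell gene Cd4 stood at -0.10 (adjusted p = 0.924), the adipocyte genes Fabp4 and Car3 at 1.63 and -1.15 (adjusted p = 0.0616 and 0.0672), and the cartilage genes Hapln1 and Sox6 at -0.68 and 0.17 (adjusted p = 0.0888 and 0.695), none of them called over all libraries. Fabp4 was called without HKO 2 (log2 fold change 0.67, adjusted p = 0.0419) or HKO 3 (adjusted p = 0.0349), and Car3 without HKO 2 (-1.58, adjusted p = 0.0137) or WT 2 (adjusted p = 0.0477).

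The tests of the clock genes, of mitochondrial counts and of dilution by other cells were chosen after the result was seen. The 6 libraries make 10 splits into 3 and 3, too few for a share below 0.05. The real split gave 1516 genes higher and 1401 lower. The highest count in either direction among the other splits was 1 gene, so that 1 of the 10 splits gave as many in each direction. Every other split mixes the genotypes within both groups. A strong difference between HKO and WT, whatever its cause, thus widens the spread within those groups and leaves few calls. These counts therefore do not measure what chance alone would give. For the lists, the real split called 19 higher and 6 lower, and other splits called up to 15 in 1 direction. The direction of another split is arbitrary, so the larger of its higher and lower counts was taken. On that count 1 of the 10 splits gave as many as 19 and 10 of the 10 gave as many as 6. Part of the genotype difference stays between the groups of the other splits, so their list calls need not be false.

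Large changes near the targeted Sox9 allele and near the ROSA26 locus, a common site for transgenes, were weighed against DNA of another strain carried along with an engineered locus. BC018473 (chromosome 11, 116752167 to 116759373), a non-coding gene 3.97 Mb from Sox9, was at 0 in all WT libraries and at 6.20 ± 1.41 CPM in HKO, at least 108-fold higher against 3 counts over the WT group, and Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077333) fell with a log2 fold change of -2.95 (adjusted p = 0.000141), both named after their values were seen. Within 10 Mb of Sox9, 10 of 228 genes (4.39%) were called with an absolute log2 fold change of at least 2, against 1.89% in the median window, and 10.4% of windows had a share as high. Kpna2 (5.79 Mb) is among the 10. Around Gt(ROSA)26Sor the share was 2 of 96 genes (2.08%), and 44.4% of windows had one as high. The 2 are Cidec (0.357 Mb) and A2m (8.57 Mb). Neither share is in the top 5% of windows or at or below the median, so the shares do not decide. The WT mice are labelled Sox9f/f, so DNA linked to that Sox9 allele would be in both groups if HKO carries the same one. The sources used here do not describe the HKO allele. Strain DNA linked to another engineered locus may contribute and cannot be told apart from an effect of the genotype. For Gt(ROSA)26Sor a changed allele is a further candidate explanation that was not tested.

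The clock genes may reflect tissue collected at another time of day in the 2 groups. Under that hypothesis genes that peak with Nr1d1, Dbp and Per and genes that peak with Arntl would move in opposite directions. Their median log2 fold changes were 1.28 over 11 genes and -0.40 over 6, and the two-sided exact permutation p over genes, which are not independent replicates, was 0.0734. Nr1d1 (-2.87) went against its own group, and Cry1 (1.49), for example, went against the group that peaks with Arntl, to which it belongs. The hour of collection and the genotype cannot be told apart here, since no library of either group is labelled with an hour.

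The lower mitosis genes in HKO were weighed against 2 technical explanations. Counts taken up by mitochondrial transcripts are argued against. With library totals alone, the largest fall that the mitochondrial shares can give any HKO library against any WT library is -0.22 on the log2 scale, where the mitosis list's upper quartile was -1.62. The mitochondrial genes took 12.1%, 25.9% and 12.3% of the counts in HKO 1, 2 and 3 and 16.3%, 13.4% and 15.3% in WT 1, 2 and 3. A dilution of all hepatocyte transcripts by other cell types is argued against too, since it would lower the hepatocyte and mitosis lists alike. The hepatocyte list had a median of -0.0176 with quartiles at -0.38 and 0.26, where the mitosis list's upper quartile was -1.58. TMM holds the typical gene near 0, so only the gap between the 2 lists carries weight. That gap does not show which cells were dividing. The genotype and the hour of collection stay open as candidate explanations of the mitosis genes, and neither was tested apart from the other. HKO 2, with the highest mitosis genes of the 3 HKO libraries, also had the highest mitochondrial share (25.9%) and the highest matrix genes.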
